A study of Mus musculus with 2 samples.

How the data were processed

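Single-cell RNA sequencing was applied to CD8 T cells sorted from mouse tumors into 4 populations, which were tagged separately and captured together. Per the labels, the series holds 2 libraries of that lane, a cDNA library and a tag library. Per the submitters' processing notes, Cell Ranger 4.0.0 and the genome build mm10 were used. The settings of cell calling and the gene annotation are not given in the sources used here. The files used were the list of cell barcodes and the list of features that accompany a filtered matrix. They hold names and no measured values, so their deposited contents have no unit or normalization. Counts per cell and the assignment of cells to tags were not analysed here, and depth per cell is unknown. The labels' extract protocol describes a different preparation from the design text, which is taken up in the closing section.

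From the barcode list, the number of barcodes, their length, suffix and base use were computed, together with Cramér's V between the bases at each of the 120 pairs of positions. Cramér's V is 0 for independent bases and 1 where one base fixes the other. Pairs of barcodes 1 or 2 bases apart were counted. For comparison, 100 lists were rebuilt by shuffling the last 8 bases among barcodes with the same base at position 9, counting positions from the first base. The pair search was tested on 5000 simulated barcodes with planted copies, and found 200 of 200 copies 1 base away and 200 of 200 copies 2 bases away.

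Feature identifiers were matched without version numbers to GENCODE M21, an annotation of GRCm38, the assembly also called mm10. A total of 119 identifiers had no match, so the release behind the feature list was not the same. Coordinates are 1-based and come from GENCODE M21. In the feature list 35 symbols were carried by more than 1 gene, for 71 genes in total.

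The gene lists were fixed before the data were examined, and the genes named are their members. They comprised effector, exhaustion, progenitor and memory, tissue residency, early T cell receptor response, cell cycle and interferon response genes, and markers of CD8 T cells, myeloid cells, B cells, NK cells, dendritic cells, a melanoma line, fibroblasts, endothelial cells and erythroid cells. A member was counted as listed when its exact symbol was a feature. Partner genes such as Gm49368 are named because they overlap a member. For each member, exons of all its GENCODE M21 transcripts were merged and intersected with those of every other listed gene. The last 500 bases of each of its transcripts were cut into windows of 50 bases. Each distinct window was searched on the same strand in the GENCODE M21 transcripts of all other listed genes. The 119 identifiers without a match, Tfp and mCherry have no transcripts there, so neither comparison covered them. The read length of the libraries is not given in the sources used here, so the window length is a choice. Members with at least 10% of windows shared are named.

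No test between groups was made, because each library kind and each sorted population is 1 sample. Alternatives were collapsing near-identical barcodes, counting features by symbol, matching symbols without regard to case or through RefSeq synonyms, and other window and end lengths. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.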

Results

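The study profiled single CD8 T cells taken from mouse tumors. Donor OT-I T cells, which carry a transgenic receptor for an ovalbumin peptide, bore the CD45.1 marker and a Cd69-TFP reporter. They were recovered from B78chOVA tumors on day 12 after transfer. Sorting on the reporter protein TFP and on surface CD69 gave 4 populations, namely TFP+ CD69−, TFP+ CD69+, TFP− CD69− and TFP− CD69+. Cells of 8 tumors from separate mice were combined within each population, marked with 1 lipid-anchored oligonucleotide tag per population, and loaded together into 1 droplet capture lane. The 2 libraries were a cDNA library (n = 1) and a tag library, named ADT in the labels (n = 1). They are 2 readouts of the same lane and not 2 conditions.

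The comparison the design implies is between the 4 sorted populations, that is, which transcripts go with an active reporter and which with CD69 on the surface. The data used here were the list of cell barcodes and the list of features. Transcript and tag counts per cell were not analysed here, and cells were not assigned to the sorted populations. Sequencing depth per cell is therefore unknown, and no expression level, fold change, cell type share or difference between populations is reported. Because the mice were pooled before capture, each population is 1 sample, so a comparison between populations in this lane has no replicate error to set it against. The values below describe how many cells were called and which genes, reporters and tags the experiment was set up to count.

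The list held 18613 cell barcodes, all distinct and each 16 bases long. They shared a single suffix. The design text gave a target cell number of 18000, and the list exceeded it by 613 barcodes, or 3.41%. Merging barcodes up to 2 bases apart left 17011, which is below the number aimed for. The 1613 pairs 2 bases apart lay within the range of 1431 to 1650 found in lists rebuilt from the same barcode parts, so such a merge joins about as many barcodes as chance pairs would. A barcode is a droplet called as holding a cell. Droplets with more than 1 cell were neither identified nor removed here. No replicate lane was analysed, so the number has no replicate error.

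The feature list held 31059 entries, of which 31055 were gene expression features and 4 were antibody capture features. The capture features were named Barcode_1 to Barcode_4, the same number as the sorted populations. The list does not say which tag marked which population. Of the gene expression features, 31053 were mouse genes with Ensembl identifiers. The other 2 were the added sequences Tfp and mCherry, each listed as a feature of its own. Cd69 (ENSMUSG00000030156), which encodes an early activation antigen of lymphocytes, was listed once. It lies on the minus strand of chromosome 6, from 129267325 to 129275436 in mm10 (GENCODE M21 annotation), and its annotated exons cover 6509 bases. No exon of another listed gene found in GENCODE M21 overlapped them on either strand. None of the 50-base windows of the 3′ end of Cd69 occurred in the transcripts of such a gene. The Tfp sequence itself was not analysed here, so sequence shared between the reporter and Cd69 was not examined.

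The listed genes were mostly protein-coding. Of the 31053 identifiers, 30934 (99.6%) were found in GENCODE M21, and 21897 of those (70.8%) were protein-coding. These made up 99.8% of the 21951 protein-coding genes of that annotation. Long intergenic RNAs contributed 5459 genes and antisense RNAs 2816. All 144 V genes, 70 J genes, 4 D genes and 8 constant genes of the T cell receptor loci were listed, as were all 218 genes of the annotation's immunoglobulin V class. In contrast, none of the 2202 miRNA genes and 1507 snoRNA genes was listed, and 32 of 9940 processed pseudogenes were. The list held 13 mitochondrial genes, which are commonly used to judge cell quality, and none of the 2 mitochondrial ribosomal RNA genes.

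Genes of the T cell programs that a CD69 reporter sort addresses were almost completely covered under the symbols searched. So were protein-coding genes in general, with 99.8% of those in GENCODE M21 listed, so this coverage is not particular to these programs. All 12 genes of the effector list were listed, among them Gzmb, Prf1 and Ifng, which encode granzyme B, perforin and interferon gamma. Of the 10 genes of the exhaustion list, 9 were listed under the symbol searched, including the inhibitory receptors Pdcd1, Havcr2, Lag3 and Tigit and the transcription factor Tox. The remaining one, Cd244a, was listed under its older symbol Cd244. All 10 progenitor and memory genes were listed, among them Tcf7 and Il7r. The same held for all 8 tissue residency genes, including Itgae, Cxcr6 and Zfp683, and for all 10 early response genes downstream of the T cell receptor, including Nr4a1, Nr4a3 and Egr2. The 9 cell cycle genes and the 7 interferon response genes were also all listed. Across all lists, 110 of 111 distinct genes were found under the exact symbol. These counts say that a gene could be counted, and carry no information on whether it was expressed.

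The fixed marker lists for other cells that a tumor sort could carry over were fully covered as well. This was again in a feature list that held nearly all protein-coding genes. The CD8 T cell list had 6 of 6 genes listed, including Cd3e, Cd8a and Trac. The lists for other types were at 8 of 8 for myeloid cells, 5 of 5 for B cells, 5 of 5 for NK cells, 6 of 6 for dendritic cells, 6 of 6 for the melanoma line, 5 of 5 for fibroblasts, 3 of 3 for endothelial cells and 4 of 4 for erythroid cells. Whether the B78chOVA tumor line expresses the melanoma line markers was not examined, and the added feature mCherry was in none of the lists. Whether any of these cells were present was not analysed here.

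Sequence shared with another listed gene affected 11 of the 111 genes at their 3′ ends, counting genes with at least 10% of their 50-base windows in the last 500 bases also found in another listed gene. With windows of 90 bases it was 7 genes, without Cd8b1, Ifit3, Klra8 and Lyz2. Windows were pooled over the ends of all annotated transcripts of a gene, 1547 for Itgam and 451 for Cd8b1. The percentages therefore do not tell which transcript end was shared, or which ends were in use. The hemoglobin genes shared most, with 91.1% of windows for Hba-a1 and 88.3% for Hba-a2, each with the other, and 64.5% for Hbb-bt and 56.1% for Hbb-bs, again with each other. Itgam, the integrin CD11b used as a myeloid marker, shared 30.1% with the predicted gene Gm49368, whose exons covered 68.7% of its exonic bases on the same strand. Pcna, a replication clamp gene of the cell cycle list, shared 20.99% with Pcna-ps2. Cd8b1, the CD8 beta chain, shared 19.1% with transcripts of 21 other listed genes. Among NK cell markers, Klrb1c shared 17.4% with Gm44511, Klrb1a and Klrb1b, and Klra8 shared 13.1% with Klra10, Klra3 and Klra9. Lyz2 shared 16.9% with Lyz1, and Ifit3 shared 14.9% with Ifit3b. None of the effector, exhaustion, progenitor and memory, tissue residency or early response genes reached 10%, although Tigit did when windows of 30 bases were used. The highest among these were Il7r, at 2.23%, and Itga1 and Tigit, at 0.222% each. Under the 3′ kit of the design text, counts of these genes are uncertain to the extent that reads fall wholly in the shared part, which for Cd8b1, Ifit3, Klra8 and Lyz2 was under 10% of windows at 90 bases. The labels' protocol names a 5′ kit, and 5′ ends were not examined.

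**Figure D1:**
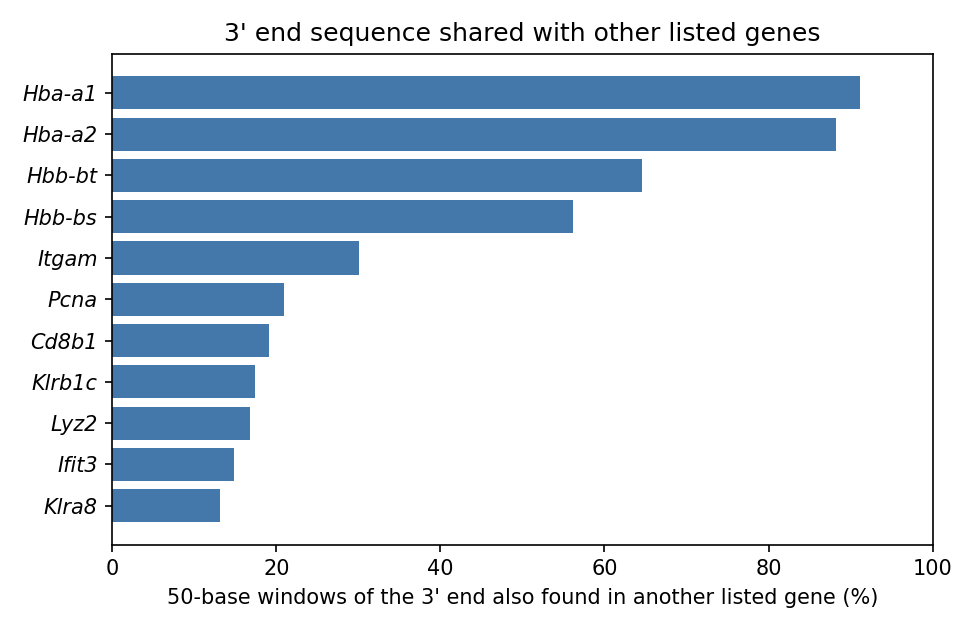
Share of the 50-base windows in the last 500 bases of each gene's annotated transcripts that also occur in another listed gene (x axis, percent), for the 11 list genes at 10% or more (y axis, gene symbols). Each bar is 1 gene computed from sequence, with no replicates; the 4 hemoglobin genes lie between 56.1% and 91.1% and the others between 13.1% and 30.1%.

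Exons of other listed genes overlapped 4 list genes on the same strand and 11 on the opposite strand. On the same strand these were Itgam, Klrb1c with 13.9% of its exonic bases under Gm44511, Clec9a with 5.59% under Clec1b, and Itga1 with 3.68% under Gm49395. On the opposite strand the largest overlaps were 15.1% for Csf1r with Hmgxb3 and 13.7% for Lef1 with Gm43352. Jun followed with 7.28% under its antisense gene Junos. In Tox, 3.42% of exonic bases lay opposite Gm11802. A total of 82 of the 111 genes had neither kind of overlap and no shared 50-base window in the last 500 bases. At that setting 18 genes shared at least 1 window. It was 39 genes with windows of 30 bases and 10 with windows of 90 bases. With 50-base windows it was 15 for the last 300 bases and 24 for the last 1000. The 82 was not recomputed for those settings.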

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

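The alternatives on barcodes up to 2 bases apart, on synonyms and on window lengths were chosen after seeing the data. Collapsing barcodes 1 base apart left 18613, and collapsing those up to 2 bases apart left 17011, which turns the excess over the 18000 cells aimed for into a shortfall. The 1613 pairs 2 bases apart behind this were about as many as in rebuilt lists (median 1553.5). Counting gene features by symbol gave 31019 instead of 31055. Ignoring letter case left 110 of the 111 list genes matched, and RefSeq synonyms brought this to 111. The count of 11 genes sharing at least 10% of their 3′ end became 7 with windows of 90 bases, where Cd8b1, Ifit3, Klra8 and Lyz2 fell under 10%, since a longer window requires a longer identical stretch. It was 12 with windows of 30 bases, where Tigit was added, so the statement that no exhaustion gene reached 10% holds only for the longer windows. It was 10 for the last 300 bases, without Ifit3, and 11 for the last 1000 bases, with Fcgr3 in place of Cd8b1. Filters on genes or mitochondrial share per cell, doublet removal, thinning to a fixed number of transcripts and a restriction to CD8 T cell-like clusters were not run, since counts per cell were not analysed here. No paired analysis was possible because no result comes from a test between groups.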

Other observations

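The labels and the feature list describe different tag panels. The labels' extract protocol gives a panel of 137 antibodies and a 5′ kit, applied to a mixture of CD45+ and CD45− cells. The design text gives lipid-anchored tags and a 3′ kit, applied to sorted T cells. The feature list held 4 capture features, which is the number of sorted populations, and no panel of 137. The sequence sharing reported above was computed for 3′ ends only, so it bears on the counts under the 3′ kit of the design text. For a 5′ kit the other ends of the transcripts would matter, and these were not examined.

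The 18613 barcode sequences had an internal structure. They were not compared with the set of barcodes that the kit allows, so the structure is not read as a trait of the cells or the lane. Of the 16 possible base pairs at positions 8 and 9, 4 occurred, so the base at position 8 fixed the base at position 9 (Cramér's V of 1). The combinations were T then C in 25.9% of barcodes, A then G in 25.1%, G then T in 24.5% and C then A in 24.5%. Among the other 119 pairs of positions the highest value was 0.117, for positions 4 and 5. Across the 2 parts of the barcode, positions 1 to 8 against 9 to 16, it was at most 0.0413 once the pair of positions 8 and 9 was left out. That value was for positions 8 and 12, and positions 9 and 12 gave the same, because position 8 fixed position 9. With position 8 left out altogether, the highest value across the parts was 0.0182, for positions 7 and 13. The first 6 bases took 960 of 4096 possible sequences, and each of the 960 was followed by a single base at position 7. Single-base composition alone did not show this, with every base between 23.0% and 28.2% at every position. A simulation of barcodes as independent bases would therefore draw from a larger set of sequences than the list does.

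The list exceeded the number of cells aimed for by 613, and one hypothesis is that erroneous copies of true barcodes may have been listed as extra cells. The test at 2 bases was chosen after seeing the data. Of the listed barcodes, 0 had another listed barcode 1 base away, so the list holds no single-base copy beside its original. The 100 rebuilt lists held 0 or 1 such pair, so the structure of the barcodes by itself leaves almost none, and the count says nothing on how often such errors arose. Against copies 2 bases away, 1613 pairs were found, against a median of 1553.5 and a range of 1431 to 1650 in the rebuilt lists. The rebuilt lists held 18548 to 18582 distinct barcodes, slightly fewer than the real one. The real count minus the highest rebuilt count was -37, against the 613 that this hypothesis needs. Every listed barcode kept the pairing of positions 8 and 9, so copies that broke it were absent, whatever their rate. If the list was restricted to barcodes that the kit allows, which was not examined, both counts were limited in advance. The 2 counts therefore describe the list, and cannot decide how often copying errors arose before it was made. Droplets without a cell that were called as one and a number of captured cells above the target remain open. With 1 lane the usual spread around a target is unknown, so the excess of 613 may need no particular cause. No biological explanation was tested.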
